A study of Mus musculus with 4 samples.

How the data were processed

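RNA-seq was measured in 4 libraries of CT26, a mouse colon carcinoma cell line. Per the labels, total RNA was extracted with an RNeasy kit and made into libraries with a SMARTer mRNA-seq kit. The deposited file gives FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for each gene and library, as the authors computed it. The aligner, the quantification tool and the strandedness are not given in the sources used here. The submitters' processing notes name the genome builds GRCm38 and mm10, which are 1 assembly under a pair of names. The file lists 55335 Ensembl gene identifiers, of which 55154 (99.67%) are in the GENCODE M21 annotation that was used here for positions, gene types and exonic lengths. Of these identifiers, 27670 were above 0 in at least 1 library.

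Sample groups were taken from the submitters' labels. The labels put 2 libraries in a group labelled FOSL2 wild type with PBS and 2 in a group labelled FOSL2 knockout with chemoradiotherapy. Genotype and treatment change together between these groups, so their effects cannot be separated. The titles give a second division, a stem (CT26_102 or CT26_CTL) and a suffix (none or R), and the suffix R coincides with the group labelled FOSL2 knockout. The labels do not say what CT26_102 or R stands for, and the design text speaks of knockdown cells. Both divisions were tested, the labelled group difference (suffix R minus none) and the title stem difference (CT26_102 minus CT26_CTL), with 2 libraries on each side. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

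The file gives no read counts, so depth was estimated from the steps between low FPKM values of genes with exonic lengths of at least 300 bases. The step that 1 read makes corresponded to 21.62 M reads in CT26_102, 24.15 M in CT26_102_R, 26.37 M in CT26_CTL and 21.61 M in CT26_CTL_R. Between 26.89% and 28.05% of values below 5 reads were whole numbers of reads within 0.02 reads, so these depths are approximate. At these depths 1 read in a transcript of 2 kilobases corresponds to between 0.01896 and 0.02314 FPKM. No confidence intervals for counts were computed, since the counts themselves are not in the values used.

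Genes with an FPKM of at least 1 in at least 2 libraries were kept, which left 11955 genes. Values were analysed as log2(FPKM + 1) with no further scaling, so folds of genes with low values are understated. R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) gave two-sided p-values, adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. The first fit held the tested division alone. A second fit, fixed together with it, held both the title stem and the labelled group as terms and is called the two-factor fit here. Its 1 residual degree of freedom is the interaction of stem and group, and limma's prior added 4.01 degrees of freedom. Because the count of genes differed by more than 1.5 times between both fits, both are given. The words rose and fell refer to genes past the adjusted threshold in the two-factor fit, unless the fit without the second term is named. Errors written with ± are standard errors of the fit without the second term. With 2 libraries against 2, an exact two-sided permutation test of a single gene cannot give a p below 0.333, so none was run.

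Gene lists were tested with camera (limma), which compares a list with all other tested genes, at a preset correlation of 0.01. Adjustment was over the 31 of 35 lists that had at least 5 tested members. The lists were written from general knowledge before the data were examined, as were the tests and their alternative settings. They cover the AP-1 family, type I interferon response, antigen presentation by MHC class I and class II, chemokines, cytokines and growth factors, immune checkpoints, NF-kB targets, p53 targets, mitosis, S phase and double-strand break repair. Others cover hypoxia and glycolysis, the unfolded protein response, heat shock, NRF2 targets, extracellular matrix, epithelial genes, cholesterol synthesis, fatty acid synthesis, YAP/TEAD targets, MAPK feedback and immediate early genes, and MYC targets. The rest cover cytosolic ribosomal proteins, nuclear and mitochondrial genes of oxidative phosphorylation, long noncoding RNA, senescence-associated secretory genes, apoptosis, nucleic acid sensing, and markers of T and NK, myeloid, fibroblast, endothelial and erythroid cells. Some genes are in several lists, such as Cxcl1 in those of chemokines, NF-kB targets and secretory genes. List results are therefore not independent. The secretory list also holds Cdkn1a, which encodes a cell cycle inhibitor and not a secreted factor. Each list was also tested with an estimated correlation and with fry, a rotation test of direction that does not compare a list with other genes. The test with an estimated correlation has only the residual degrees of freedom of the fit, 2 without the second term and 1 with it. Few lists could pass it whatever their correlation, so a call lost there does not show that correlation made the call. The AP-1 list, with an estimated correlation of 0.00604 between labelled groups, went from adjusted p = 0.0413 to 0.490. Estimates for other lists ran from below 0, as for S phase (-0.0126), to 0.180 for mitosis, 0.354 for p53 targets and 0.470 for cytokines. Where the correlation exceeds the preset 0.01, p-values at the preset may be too small. For such lists a lost call leaves open whether correlation made it. For each difference between 2 single libraries, a list median was ranked among the medians of 10000 random lists of the same size matched on mean expression, which gives a percentile and no p-value.

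Genes were chosen for the text by a rule fixed before the data were examined. Fosl2 came first. For each division the rule took the 12 highest and 12 lowest log2 differences among genes past the threshold that moved the same way in both library pairs, had a mean FPKM of at least 5 in the higher group and had a symbol that is not a predicted gene. Open places were filled by genes that met the other conditions, ranked by the smaller of their 2 pair differences. Of each list, up to 4 members with the largest absolute difference in 1 direction were added. The text gives a selection of these genes, and a gene outside the rule is named as such.

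Alternative settings were a pseudocount of 0.1, no expression filter, a filter at FPKM 5, rescaling by median-of-ratios factors or to a common upper quartile, eBayes without trend or with robust settings, the second term, and leaving out each library in turn. After seeing the data, the same settings were tried with the two-factor fit, and all counts were repeated on protein-coding genes with exonic lengths of at least 200 bases. A check of pairing gave correlations across genes of 0.723 between deviations of libraries that share a stem and 0.655 between those that share a suffix.

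Further descriptions used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. The trend of differences with exonic length was fitted by lowess (share 0.3) over 11949 genes and subtracted. Medians were taken in windows of 40 neighbouring protein-coding genes, every 5 genes along each chromosome, and compared with 100 shuffled gene orders. Limits of list medians are 95% bootstrap limits over genes (2000 resamples). They treat the genes of a list as independent and do not cover the spread between libraries. Genes were counted as present in 1 stem alone at FPKM of at least 5 in both of its libraries and at most 0.5 in both others.

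The fits were tested on simulated data with 200 changed genes among 11955. With no stem difference, both fits recovered 100% of them, with 10 false calls without the second term and 7 with it. With stem differences as wide as in the data, the fit without the second term recovered 0%, 2.99% and 65.2% of genes changed by 2, 4 and 8 times, and the two-factor fit recovered 100% with 5 false calls. Simulated genes of like expression shared 1 spread and had no interaction of stem and group. These figures therefore do not give the power or false calls in the real data. There Ddit3, with a labelled group difference of 1.58, did not pass (two-factor adjusted p = 0.0677). The list test found the shifted list and called 0 of 30 others. The simulated genes were independent, whereas estimated correlations between labelled groups reached 0.66 for ribosomal proteins and 0.68 for long noncoding RNA. The simulation therefore does not show how often correlated lists are called falsely. The window search found 3 of 3 planted segments with 0 windows called elsewhere.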

Results

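Gene expression was measured by RNA-seq in 4 libraries of CT26 cells, a colon carcinoma line of the mouse, as FPKM per gene. The libraries titled CT26_102 and CT26_CTL are labelled FOSL2 wild type with PBS. Those titled CT26_102_R and CT26_CTL_R are labelled FOSL2 knockout with chemoradiotherapy. Each title is 1 library, so each labelled group held 2 libraries and each title stem held 2. Estimated depth was between 21.61 and 26.37 M reads (M for mega). FPKM was at least 1 for 11782 genes in CT26_102, 11904 in CT26_102_R, 11328 in CT26_CTL and 11280 in CT26_CTL_R. The 10 most abundant genes took between 12.38% and 15.22% of total FPKM, and mitochondrially encoded genes took 12.04%, 12.27%, 9.367% and 9.094% in the order CT26_102, CT26_102_R, CT26_CTL and CT26_CTL_R, which holds wherever 4 values are listed.

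The series title concerns FOSL2, T cell infiltration and the response of rectal cancer, so Fosl2 was examined first. Fosl2 (ENSMUSG00000029135, GRCm38 chromosome 5, 32135801 to 32157842, plus strand) encodes a subunit of the AP-1 transcription factor. Its FPKM was 9.35, 16, 12.7 and 19.2. Fosl2 transcript was thus higher in both libraries labelled FOSL2-KO than in their partners of the same stem, by 1.64 and 1.48 times, so the transcript did not follow the genotype labels. The log2 difference was 0.64 ± 0.24 (SE, n = 2 libraries per group, adjusted p = 0.464), and with both terms in the fit the adjusted p was 0.0444. Between stems Fosl2 was lower in CT26_102, at 0.756 and 0.839 times CT26_CTL, a log2 difference of -0.33 ± 0.35 (adjusted p = 0.670, or 0.130 in the two-factor fit). With library CT26_102 left out, the difference turned to 0.0282. That fit set CT26_102_R alone against both CT26_CTL libraries with no term for the suffix. It therefore mixes stem with suffix and does not reverse the direction seen in both matched pairs. No library lacked the transcript.

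Between the labelled groups, 30 of 37 p53 targets rose, and 18 of 41 mitosis and G2/M genes fell while 23 did not pass. Neither list passed with an estimated correlation (adjusted p = 0.490), a test with 2 residual degrees of freedom that few lists could pass. Mdm2 (ENSMUSG00000020184, chromosome 10, 117688875 to 117710758), which encodes the ubiquitin ligase that degrades p53, rose from 47.2 to 486 in stem CT26_102 and from 38.5 to 292 in stem CT26_CTL. Its log2 difference was 3.11 ± 0.32 (SE, n = 2 per group, adjusted p = 0.266 in that fit without the stem). In the two-factor fit, which has a smaller error, the adjusted p was 0.00886. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), the inhibitor p21 that halts the cell cycle, rose from 92.2 to 359 and from 94.6 to 377 FPKM, 1.97 ± 0.19 on the log2 scale (adjusted p = 0.266 without the stem, 0.00886 in the two-factor fit). Ccnb2 (ENSMUSG00000032218, chromosome 9, 70407692 to 70421547), a mitotic cyclin, dropped from 48.8 to 18.8 and from 37.9 to 11.8, a log2 difference of -1.47 ± 0.30 (adjusted p = 0.413 without the stem, 0.0179 in the two-factor fit). These directions are those of the libraries labelled FOSL2-KO with chemoradiotherapy, in which Fosl2 itself was higher and genotype and treatment cannot be separated.

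The comparison asked which genes differ between the labelled groups. In the fit without the stem, 1 gene of 11955 passed and 1281 had an unadjusted p under 0.05. In the two-factor fit, 905 genes rose and 636 fell, 58.7% of calls upward, while 0 genes passed in that fit without the expression filter (27670 genes tested). With upper-quartile rescaling of the two-factor fit, 937 rose and 1011 fell, so the balance of directions depended on the scaling, while the median of all genes moved only to -0.05. The log2 differences in stem CT26_102 and in stem CT26_CTL had a correlation across genes of 0.655 (Pearson) and 0.693 (Spearman), where genes are not independent replicates. Of 309 genes that differed by over 2 times in both stems, 286 did so in the same direction, 204 higher and 82 lower in the libraries labelled FOSL2-KO. The single gene past the threshold without the stem was AC147560.1 (ENSMUSG00000104953), an annotated microRNA locus of 107 bases on chromosome 9, 64726624 to 64726730. It was at 41.0 and 43.9 FPKM in the libraries labelled wild type and under the value of 1 read in both others. It is named after its values were seen, and a locus this short is poorly measured by mRNA libraries. Both Snord57, a small nucleolar RNA at 18.4, 0.0385, 12.2 and 0.0282 FPKM, and this locus are therefore uncertain.

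**Figure D1:**
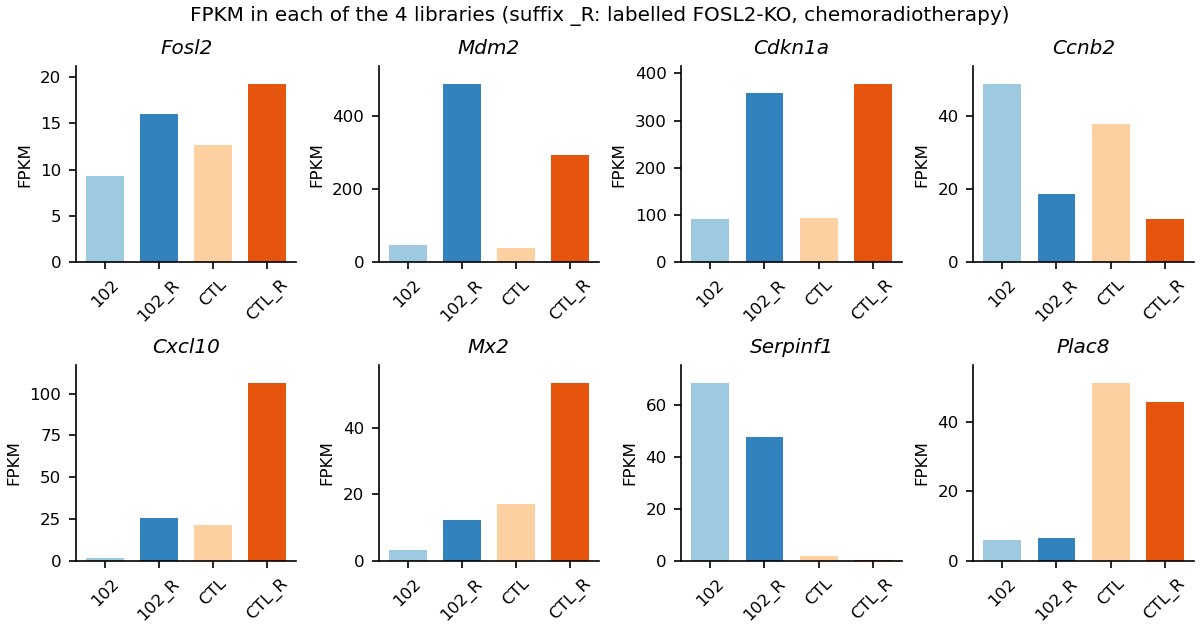
FPKM (vertical axis, linear from 0) of 8 genes in each of the 4 libraries, 1 bar per library and no error bars since each title is 1 library. Mdm2 stands at 486 and 292 FPKM in the libraries with suffix R and at 47.2 and 38.5 in the others, while Serpinf1 separates by stem, at 68.4 and 47.8 against 1.88 and 0.496.

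Of 37 measured p53 targets, 30 rose, 0 fell and 7 did not pass, and 32 rose when adjusted over the list alone. Btg2, an antiproliferative gene, reached 83.7 and 51.8 FPKM from 5.78 and 5.62, and Trp53inp1, a stress-induced p53 cofactor, reached 69.4 and 23.8 from 10.7 and 2.88. The death gene Bbc3 (PUMA) was at 10.0, 33.9, 13.2 and 53.5, Bax at 90.1, 178, 107 and 197, and the death receptor Fas at 1.44, 17.9, 0.424 and 4.19 FPKM, whereas of 28 apoptosis, pyroptosis and necroptosis genes 6 rose, 0 fell and 22 did not pass, the same when adjusted over the list alone (adjusted p = 0.230). The p53 list median was 1.31 log2 units (adjusted p = 5.1e-17). The list did not pass with its estimated correlation of 0.354 (adjusted p = 0.490), where power was low. At that correlation the p-value from the preset may be too small. Of 41 mitosis and G2/M genes, 0 rose, 18 fell and 23 did not pass, and 1 rose and 28 fell when adjusted over the list alone. Plk1, a mitotic kinase, was at 58.4, 24.1, 38.7 and 14.4 FPKM, Ccna2, cyclin A, at 56.7, 26.9, 42.0 and 15.8, and the centromere protein gene Cenpf at 16, 5.43, 6.40 and 2.15. The list median was -0.56 (adjusted p = 1.8e-11, or adjusted p = 0.490 with an estimated correlation of 0.180). In each stem the p53 list stood at percentile 100 and the mitosis list at percentile 0 of random lists.

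Lists of DNA replication and repair had negative medians in the libraries labelled FOSL2-KO with chemoradiotherapy, though most of their genes did not pass. Of 45 S phase genes, 2 rose and 7 fell, and 2 rose and 10 fell when adjusted over the list alone (median -0.24, adjusted p = 0.00435, or adjusted p = 0.490 with an estimated correlation). Thymidine kinase Tk1 was at 16.5, 6.82, 14.4 and 7.18 FPKM and the helicase subunit Mcm6 at 39.8, 21.5, 33.5 and 19.1. Fen1, the flap endonuclease of replication and base excision repair, went the other way, from 8.37 to 27.9 and from 8.64 to 27.1. Of 44 double-strand break repair genes, 0 rose and 7 fell, and 1 rose and 14 fell when adjusted over the list alone (median -0.35, adjusted p = 9.8e-05, or adjusted p = 0.490 with an estimated correlation). H2afx, the histone marked at breaks, was at 24.9, 9.99, 25.4 and 11.1, and the checkpoint kinase Chek2 at 11.6, 6.70, 11.9 and 5.94 FPKM. The linker histone H1f0 fell from 183 to 46.5 and from 390 to 67.1 FPKM.

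Medians of 3 metabolic lists were negative. Of 30 hypoxia and glycolysis genes, 0 rose and 13 fell, and 19 fell when adjusted over the list alone (median -0.58, adjusted p = 1.5e-05, or adjusted p = 0.490 with an estimated correlation). Pdk1, which encodes a kinase that inhibits pyruvate dehydrogenase, was at 17.4, 3.86, 12.5 and 4.2 FPKM, and the mitophagy gene Bnip3 at 78.9, 31.6, 121 and 59.2. Of 22 cholesterol synthesis genes, 0 rose and 5 fell, and 9 fell when adjusted over the list alone (median -0.42, adjusted p = 8.7e-05, or adjusted p = 0.490 with an estimated correlation). Hmgcs1, the synthase upstream of mevalonate, was at 36.2, 13.4, 17.5 and 10.6. Of 19 fatty acid synthesis genes, 1 rose and 6 fell, and 1 rose and 11 fell when adjusted over the list alone (median -0.49, adjusted p = 0.00012, or adjusted p = 0.490 with an estimated correlation). The desaturase Scd2 was at 59.0, 14.3, 20 and 8.29 and the elongase Elovl6 at 13.4, 4.46, 5.91 and 2.64 FPKM. Of 56 nuclear genes of oxidative phosphorylation, 11 rose and 1 fell, and 15 and 2 when adjusted over the list alone (median 0.24, adjusted p = 0.0103, or adjusted p = 0.700 with an estimated correlation). Uqcr10 of complex III was at 126, 229, 167 and 276 FPKM and cytochrome c, Cycs, at 51.9, 113, 94.8 and 152.

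The lists of cytokines, chemokines, NF-kB targets and secretory genes had positive medians in the libraries labelled FOSL2-KO with chemoradiotherapy, though many of their genes did not pass. Of 20 cytokines and growth factors, 9 rose and 0 fell, and 11 rose and 1 fell when adjusted over the list alone (median 0.71, adjusted p = 0.000874, or adjusted p = 0.562 with an estimated correlation). Ifnb1, which encodes interferon beta, was at 0.0543 and 0.458 FPKM without the suffix and at 5.17 and 26.4 with it. Csf2, the growth factor GM-CSF, rose from 0.0578 to 7.55 and from 4.36 to 37.4, and the EGF receptor ligand Areg from 3.05 to 44.6 and from 23.9 to 96.5. Of 8 chemokines, 4 rose and 0 fell, and 5 rose when adjusted over the list alone (median 1.22, adjusted p = 0.0324, or adjusted p = 0.490 with an estimated correlation). Those that rose included Cxcl10 at 2.02, 25.8, 21.5 and 106 and Ccl5 at 1.14, 5.61, 5.47 and 28.7 FPKM, both ligands that attract T cells. Of 26 NF-kB targets, 7 rose and 0 fell, and 9 rose when adjusted over the list alone (median 0.42, adjusted p = 0.0160, or adjusted p = 0.490 with an estimated correlation), with Cxcl1 at 0.963, 10.8, 11.1 and 77.0. Of 17 genes of the senescence-associated secretory list, 9 rose and 2 fell, and 12 and 3 when adjusted over the list alone. The median of that list was 1.06 (adjusted p = 0.0103, or adjusted p = 0.515 with an estimated correlation). It shares Cxcl1 with the chemokine and NF-kB lists and Areg with the cytokine list, and it includes Cdkn1a.

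Of 14 AP-1 genes, 4 rose and 0 fell, and 5 rose and 1 fell when adjusted over the list alone (median 0.46, adjusted p = 0.0413, or adjusted p = 0.490 with an estimated correlation). Besides Fosl2, these included Jun at 30.5, 70.1, 39.2 and 87.5, Junb at 20.6, 56.9, 42.1 and 87.6, and Maff at 9.04, 43.0, 16.8 and 101.8 FPKM. Of 39 type I interferon response genes, 12 rose and 0 fell, and 13 rose when adjusted over the list alone. That list passed in the two-factor fit alone (median 0.17, adjusted p = 0.000765, against 0.176 without the stem and adjusted p = 0.481 with an estimated correlation). The antiviral GTPase gene Mx2 was at 3.38, 12.5, 17.0 and 53.5 FPKM. Ifit3b, which may share reads with Ifit3, was at 4.61, 13.3, 25.1 and 68.1. A further 3 lists passed in the two-factor fit alone. Of 22 MHC class I genes, 3 rose and 0 fell, and 6 rose when adjusted over the list alone (adjusted p = 0.0355, or adjusted p = 0.481 with an estimated correlation), among them the peptide transporter Tap1 at 8.20, 16.3, 6.91 and 12.5. Of 29 MAPK feedback and immediate early genes, 8 rose and 1 fell, and 13 and 1 when adjusted over the list alone (adjusted p = 0.0250, or adjusted p = 0.481 with an estimated correlation), with Egr1 at 31.8, 73.1, 124 and 237. Of 38 genes of the unfolded protein and integrated stress responses, 3 rose and 8 fell, and 4 and 11 when adjusted over the list alone (median -0.25, adjusted p = 0.0250, or adjusted p = 0.562 with an estimated correlation). Pck2, a mitochondrial phosphoenolpyruvate carboxykinase, and Aldh1l2, a folate enzyme, were among those that fell, at 16.4, 5.81, 20.3 and 7.88 and at 16.5, 6.62, 28 and 8.90 FPKM.

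In all, 13 of 31 lists passed without the stem and 17 in the two-factor fit, and 0 did so with an estimated correlation, where the residual degrees of freedom left little power. The remaining lists had adjusted p between 0.0650 for immune checkpoints and 0.882 for MYC targets without the stem. In the former, the T cell costimulator gene Cd80, also counted among p53 targets, rose from 11 to 64.2 and from 12.6 to 59.1 FPKM. Apoptosis (0.230), nucleic acid sensing (0.259), mitochondrially encoded genes (0.197), long noncoding RNA (0.116), ribosomal proteins (0.321), YAP/TEAD targets (0.414), heat shock, NRF2 targets and fibroblast markers (each 0.404), myeloid markers (0.408), extracellular matrix (0.487) and epithelial genes (0.618) did not pass. The median of the extracellular matrix list, 0.03, and of the myeloid list, 0.03, turned negative with upper-quartile rescaling. Longer genes were relatively lower in the libraries with suffix R, with medians from 0.15 in the shortest quintile of genes to -0.15 in the longest. With that trend removed, the oxidative phosphorylation median went from 0.24 to 0.16 and the double-strand break repair median from -0.35 to -0.24. Gene length may thus carry part of these shifts, whereas the p53 median went from 1.31 to 1.35.

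**Figure D2:**
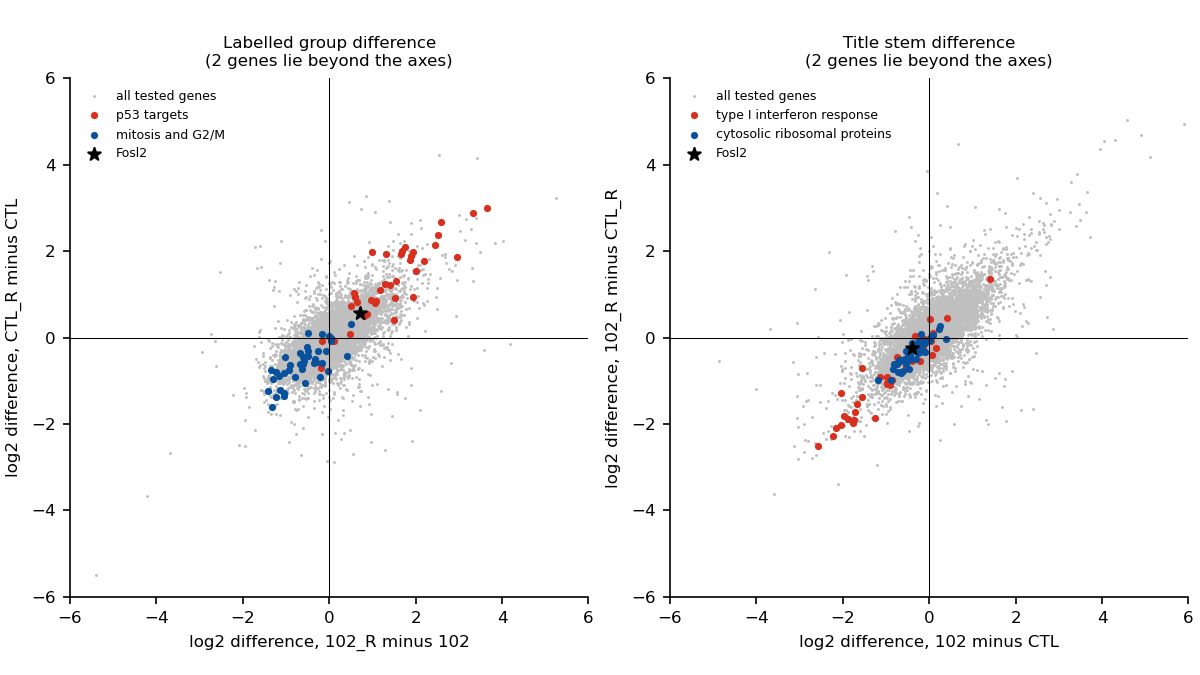
Each point is 1 of 11955 tested genes, placed by its log2(FPKM + 1) difference in 1 pair of libraries (horizontal) and in the other pair (vertical), for the labelled group (left) and the title stem (right), with 2 genes beyond the axes on each side. The p53 targets lie mostly in the upper right and mitosis genes in the lower left of the first panel, and interferon response and ribosomal protein genes lie mostly in the lower left of the second, with correlations across genes of 0.655 and 0.723.

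Between title stems, some genes were expressed in stem CT26_102 and near 0 in stem CT26_CTL, and 25 of 39 interferon response genes were lower in stem CT26_102. Serpinf1 (ENSMUSG00000000753, chromosome 11, 75409769 to 75422701), which encodes the antiangiogenic factor PEDF, was at 68.4 and 47.8 FPKM in CT26_102 and CT26_102_R against 1.88 and 0.496 in CT26_CTL and CT26_CTL_R, a log2 difference of 4.81 ± 0.39 (SE, n = 2 per stem, adjusted p = 0.0367). The chromatin-associated gene Dppa4 (ENSMUSG00000058550, chromosome 16, 48283733 to 48294237) was at 15.4 and 22.3 in stem CT26_102 and listed at 0 in both CT26_CTL libraries. Plac8 (ENSMUSG00000029322, chromosome 5, 100553725 to 100572245) was lower in stem CT26_102, at 5.97 and 6.47 against 51.1 and 45.6, a log2 difference of -2.77 ± 0.20 (adjusted p = 0.0344). Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731), an interferon-induced antiviral gene, was at 7.53, 20.3, 50 and 121 FPKM (two-factor adjusted p = 0.00316).

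The labels do not say what distinguishes the stems, so this comparison asked only which genes differ between them. Without the suffix in the fit, 34 genes passed, 28 higher and 6 lower in stem CT26_102, and 2000 had an unadjusted p under 0.05. In the two-factor fit 2623 genes passed, 1494 higher and 1129 lower, and all 34 were among them, while 0 genes passed in that fit without the expression filter. With median-of-ratios rescaling of the two-factor fit, 1190 were higher and 1312 lower. The differences without and with suffix R had a correlation across genes of 0.723 (Pearson) and 0.724 (Spearman), and of 518 genes over 2 times apart in both pairs, 501 went in the same direction. Among genes past the threshold without the suffix were the pseudokinase receptor Ptk7 at 15.7, 24.4, 0.0852 and 0.236 FPKM, the receptor Fgfr1 at 6.98, 6.57, 0.130 and 0.234, and the secreted proteins Thbs1 at 67.3, 59.0, 5.12 and 8.04, Slit3 at 21.5, 16.8, 1.35 and 1.38, and Fbln5 at 14.9, 12.3, 0.974 and 1.31. Lower in stem CT26_102 were Phf11a, at 0.648, 0.873, 12.5 and 12.1, which may share reads with its family, and the neuronal tubulin Tubb3, listed at 0 in CT26_102 and at 0.0675, 7.70 and 5.06 in the others. A count of genes at FPKM of at least 5 in both libraries of 1 stem and at most 0.5 in both of the other gave 16 for stem CT26_102 and 2 for stem CT26_CTL. The same count for the labelled groups gave 4 and 2, and for the remaining split of the libraries it gave 0 and 0.

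Of 39 type I interferon response genes, 1 rose and 25 fell in stem CT26_102, and 2 rose and 26 fell when adjusted over the list alone (median -0.93, adjusted p = 5.2e-11, or adjusted p = 0.782 with an estimated correlation). Irf7, which amplifies interferon induction, was at 24.5, 34.1, 85.5 and 138 FPKM, and Mx2 at 3.38, 12.5, 17.0 and 53.5. Guanylate binding protein genes Gbp2 and Gbp3, whose family may share reads, were also lower, Gbp2 at 8.07, 14.8, 43.2 and 79.5. The interferon list median was 0.29 for CT26_102_R minus CT26_102 and 0.21 for CT26_CTL_R minus CT26_CTL, against -0.87 for CT26_102 minus CT26_CTL. Of 20 cytokines and growth factors, 1 rose and 8 fell, and 1 and 11 when adjusted over the list alone (median -0.66, adjusted p = 0.00335, or adjusted p = 0.782 with an estimated correlation), with Csf2 at 0.0578, 7.55, 4.36 and 37.4 and osteopontin, Spp1, at 495, 351, 1123 and 1111. Of 17 genes of the senescence-associated secretory list, 1 rose and 9 fell, and 1 and 10 when adjusted over the list alone (median -0.67, adjusted p = 0.0209, or adjusted p = 0.782 with an estimated correlation). Chemokines (0 rose and 4 fell, adjusted p = 0.0229, or adjusted p = 0.702 with an estimated correlation) and NF-kB targets (0 rose and 8 fell, adjusted p = 0.00911, or adjusted p = 0.702 with an estimated correlation) passed in the two-factor fit alone. The NF-kB list median was -0.53 without the suffix (percentile 0) and -0.097 with it (percentile 4.28), so the pair without the suffix carried most of this difference.

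Lists of ribosomal and respiratory genes had negative medians in stem CT26_102. Of 59 cytosolic ribosomal protein genes, 0 rose and 26 fell, and 35 fell when adjusted over the list alone (median -0.31, adjusted p = 8.7e-10, or adjusted p = 0.782 with an estimated correlation). Among random lists matched on expression this list stood at percentile 7.92 without the suffix and 10.32 with it. Rpl8 was at 891, 882, 1650.2 and 1740.1 FPKM and Rplp2 at 214, 230.4, 354 and 405. Of 56 nuclear genes of oxidative phosphorylation, 0 rose and 21 fell, and 1 rose and 30 fell when adjusted over the list alone (median -0.35, adjusted p = 3.2e-06, or adjusted p = 0.782 with an estimated correlation), with Ndufa1 of complex I at 66.4, 98.3, 142 and 212. Among random lists matched on expression, the oxidative phosphorylation list stood at percentile 6.04 without the suffix and 0.22 with it. Longer genes were relatively higher in stem CT26_102, from -0.16 in the shortest quintile to 0.27 in the longest, and with that trend removed both medians were -0.24. Of 10 long noncoding RNA genes, 0 rose and 3 fell, and 3 fell when adjusted over the list alone (median -0.43, adjusted p = 0.0184, or adjusted p = 0.782 with an estimated correlation), with Neat1 at 8.77, 14.3, 17.4 and 45.7. The median of this list was -0.96 without the suffix (percentile 0) and -0.12 with it (percentile 22.03), so mainly 1 pair carried this call.

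Further lists passed between stems in the two-factor fit alone. Of 37 p53 targets, 14 rose and 2 fell in stem CT26_102, and 20 and 3 when adjusted over the list alone (median 0.45, adjusted p = 0.00105, or adjusted p = 0.702 with an estimated correlation), with Ccng1 at 135, 462, 39.3 and 170 and, in the other direction, Plk2 at 33.6, 158, 106 and 366. Of 41 mitosis genes, 15 rose and 0 fell, and 17 and 1 when adjusted over the list alone (median 0.34, adjusted p = 0.00975, or adjusted p = 0.702 with an estimated correlation), with the motility receptor Hmmr at 26.8, 26.7, 13.8 and 14.2. Of 30 hypoxia and glycolysis genes, 2 rose and 8 fell, and 3 and 10 when adjusted over the list alone (median -0.24, adjusted p = 0.0266, or adjusted p = 0.758 with an estimated correlation). Among random lists this list was unremarkable without the suffix (median -0.18, percentile 30.25) and low with it (median -0.32, percentile 0.36). The 2 that rose were the carbonic anhydrase Car9, at 18.4, 7.40, 1.81 and 0.727, and the lactate exporter Slc16a3, at 12.6, 7.62, 1.99 and 0.764, while Ndrg1 was at 32.8, 86.8, 279 and 319. In all, 6 lists passed without the suffix, 11 in the two-factor fit and 0 with an estimated correlation, where the residual degrees of freedom left little power. The fry test of the two-factor fit passed for interferon response (adjusted p = 0.0320), double-strand break repair (0.0320) and mitosis (0.0337). The repair list had a stem median of only 0.11, or 0.01 with the length trend removed. Among random lists matched on expression it stood at percentile 73.57 without the suffix and 27.62 with it.

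The other lists had adjusted p of at least 0.0791 between stems without the suffix, the lowest being extracellular matrix at 0.0791. There 11 of 36 genes rose and 5 fell in the two-factor fit, and Col3a1, a fibrillar collagen, was at 53, 19.8, 0.568 and 0.144 FPKM (adjusted p = 0.0545, or 0.00325 with both terms). Fibroblast markers (0.132), MHC class I (0.202), fatty acid synthesis (0.256), nucleic acid sensing (0.168), the AP-1, unfolded protein and NRF2 lists (each 0.505), heat shock (0.481), S phase and YAP/TEAD targets (each 0.396), mitochondrially encoded genes (0.315), apoptosis (0.662) and MYC targets (0.738) did not pass. Myeloid markers, epithelial genes, immune checkpoints, cholesterol synthesis, double-strand break repair and the MAPK list each had 0.304. The S phase and MYC medians, 0.02 and 0.05, turned negative with median-of-ratios rescaling.

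**Figure D3:**
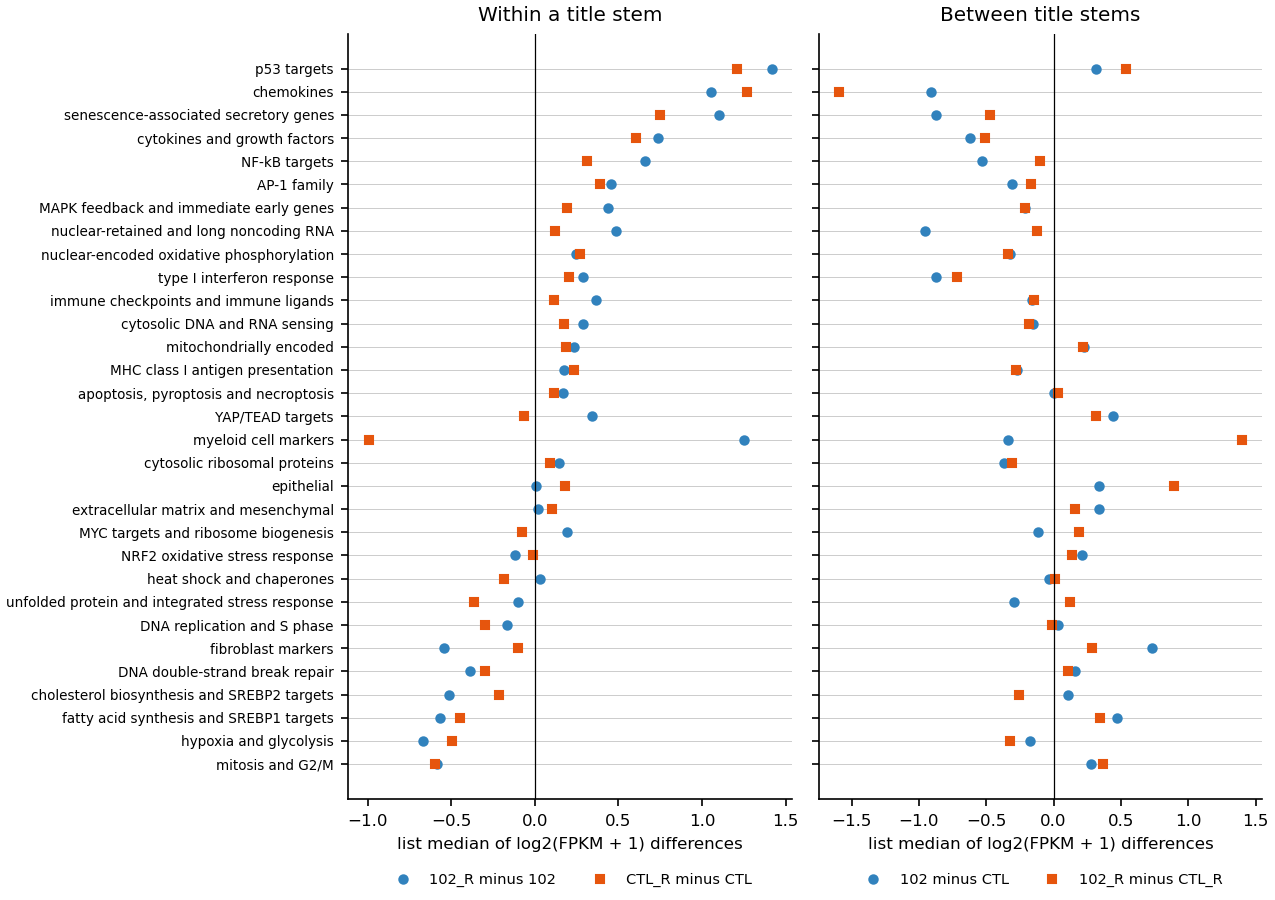
List medians of log2(FPKM + 1) differences (horizontal axis) for 31 gene lists, within each stem on the left and between stems on the right, 1 marker per pair of libraries. The p53 list lies at 1.42 and 1.21 on the left, and the myeloid list is split at 1.25 and -1.0.

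Part of the difference between stems lay in blocks of neighbouring genes. Over 1900 windows of 40 genes, the lowest window median was -0.51 and the highest 0.82 between stems, against -0.30 and 0.50 over 100 shuffled gene orders. For the labelled group the windows lay between -0.25 and 0.35, inside the shuffled limits of -0.36 and 0.37, but the spread of their medians, SD 0.09402, was above the highest of the shuffled orders, 0.087, against 0.2018 and 0.0904 between stems. Of the windows, 115 were below and 34 above all shuffled values between stems, and 0 and 0 for the labelled group. There were 8 segments beyond all shuffles in both library pairs, holding 565 tested genes, of which 241 were called between stems. They held 9.188% of the genes called between stems and 4.726% of tested genes, and 2382 called genes lay outside them. Genes on chromosome 4 from 141147913 to 149738044 (65 genes, Fbxo2 among them) and on chromosome 12 from 32378704 to 70996347 (85 genes) were higher in stem CT26_102, by 1.54 and 1.52 times at the median. Genes on chromosome 15 from 73577424 to 85463212, Rpl8 among them, were lower, at 0.718 times, with 114 of 155 lower in both pairs. Genes on chromosome 3 from 138742195 to 154623182, including Gbp2 and Gbp3, were at 0.724 times. The other lower segments lay on chromosome 15 from 12824815 to 58457740 (0.783), chromosome 5 from 8422850 to 30674830 (0.768) and chromosome X from 57053583 to 75534942 (0.726) and from 152004582 to 170019281 (0.787).

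**Figure D4:**
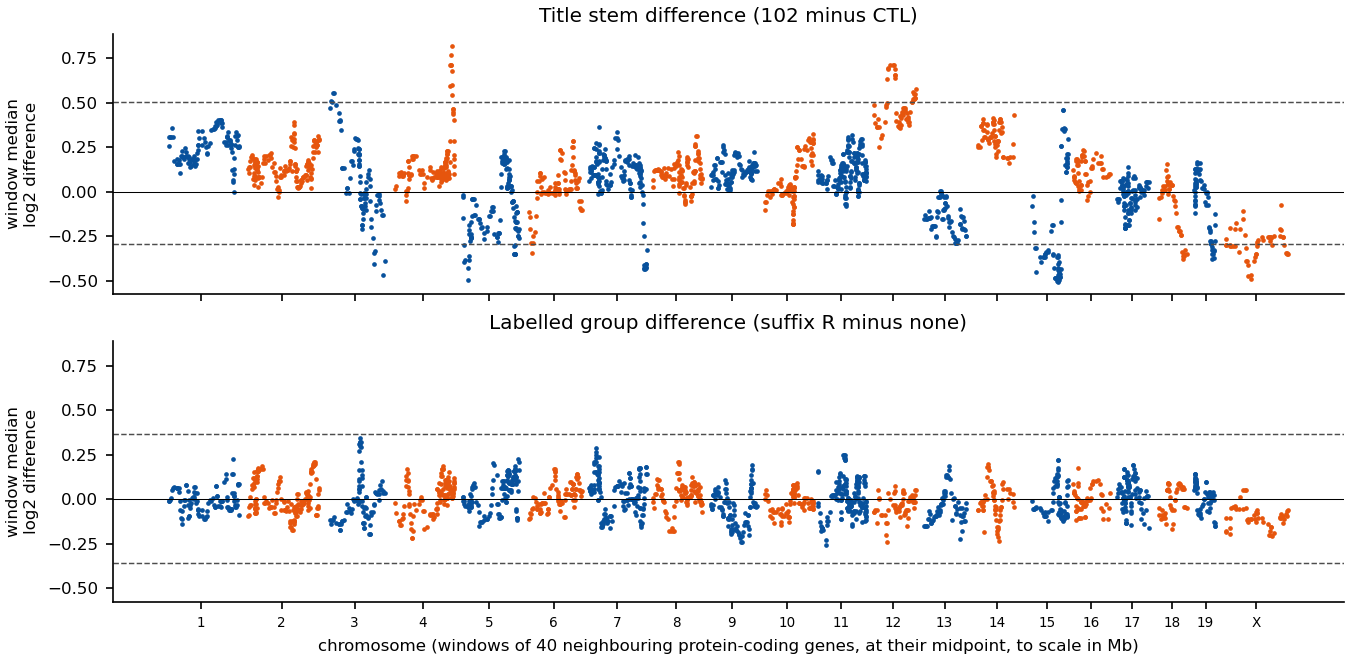
Median log2 difference (vertical axis) in windows of 40 neighbouring protein-coding genes along the chromosomes (horizontal axis, megabases to scale, GRCm38), between stems above and between labelled groups below, with dashed lines at the extremes of 100 shuffled orders. Between stems windows reach -0.51 and 0.82, and between labelled groups they stay between -0.25 and 0.35.

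Markers of T and NK, endothelial and erythroid cells were mostly near 0, whereas those of fibroblasts were not. Of 21 T and NK cell markers, 1 was above FPKM 1 in any library (Lck), as were 1 of 15 endothelial and 1 of 10 erythroid markers, and 4 of 10 for MHC class II. These 4 lists had fewer than 5 tested members and were not tested. Of 25 listed myeloid identifiers, 9 exceeded FPKM 1 and Ptprc, the pan-leukocyte gene, was at most 0.0880. Of 16 fibroblast markers, 9 exceeded FPKM 1 and 6 exceeded 10, among them Gsn at 206, 225, 114 and 163, and of 29 epithelial genes 7 exceeded 1 and 3 exceeded 10. Of the total variance over the 3 ways to split the libraries in pairs, the stem took 51.9%, the labelled group 39.8% and the remaining split, CT26_102 and CT26_CTL_R against the others, 8.34%, for which 0 genes passed in limma and 35 had an unadjusted p under 0.05.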

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

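The tests of myeloid genes and of their scaling were chosen before their results were seen, after the marker medians themselves.

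Markers of myeloid cells moved in opposite directions in the stems, which was not tested as a difference since each title is 1 library. Over 8 tested markers the median log2 difference was 1.25 for CT26_102_R minus CT26_102 and -1.0 for CT26_CTL_R minus CT26_CTL, and it was -0.33 for CT26_102 minus CT26_CTL and 1.40 for CT26_102_R minus CT26_CTL_R. Among markers named after their values were seen, lysozyme, Lyz2, was at 15, 53.1, 13.1 and 4.36 FPKM in CT26_102, CT26_102_R, CT26_CTL and CT26_CTL_R, and the signalling adaptor Tyrobp at 4.92, 13.4 and 5.09 and listed at 0 in CT26_CTL_R. Cd68 and Cd14 instead rose with the suffix in both stems, at 8.49, 63.9, 28.3 and 86.4 and at 12.4, 34.8, 22 and 38.8.

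Library scale is argued against, since the median of CT26_CTL_R minus CT26_CTL was at most -1.0 under both rescalings. RNA of myeloid cells in some libraries remains open: over the 11 genes above FPKM 0.5 in a second list of 20 myeloid genes, none of the 11 being in the first list, the median of CT26_CTL_R minus CT26_CTL was -0.38 with bootstrap limits from -0.45 to 0.43, and that of CT26_102_R minus CT26_102 was 0.32 with limits from 0.21 to 0.44. The direction is that of a small and unequal admixture, but the limits for stem CT26_CTL include 0, C1qa, C1qb and C1qc were listed at 0 in every library and Ptprc was at most 0.0880. Expression of these genes by the cells themselves may account for the pattern as well, and cannot be told apart from admixture here because each title is a single library and these genes are few.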

How the results depend on the processing

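Chosen after seeing the data were the alternatives of the two-factor fit and the restriction to protein-coding genes. For the labelled group, 1 gene passed, against 0 without the expression filter, 0 among protein-coding genes, 1541 in the two-factor fit and between 2 and 11 when 1 library was left out, each omission moving it by over 1.5 times (6 without CT26_102, 3 without CT26_102_R, 11 without CT26_CTL, 2 without CT26_CTL_R). For the stem, 34 passed, against 0 without the filter, 13 with the filter at FPKM 5, 59 among protein-coding genes, 2623 in the two-factor fit and between 0 and 16 with 1 library left out (4 without CT26_102, 16 without CT26_102_R, 7 without CT26_CTL, 0 without CT26_CTL_R). In the two-factor fit, removing the filter left 0 genes in either division (4937 and 5802 with an unadjusted p under 0.05), with 27670 genes tested in place of 11955, and every other setting stayed within 1.5 times. The two-factor fit could not be run with a library left out, since no residual degree of freedom remains. Lists past the threshold numbered 13 for the labelled group, between 9 and 21 with 1 library left out (21 without CT26_102_R), and 0 with an estimated correlation or with fry. For the stem they numbered 6, against 11 in the two-factor fit, between 7 and 14 with 1 library left out (13 without CT26_102_R and 14 without CT26_CTL), and 0 with an estimated correlation or with fry. In the two-factor fit they numbered 17 and 11, 0 and 0 with an estimated correlation, and 0 and 3 with fry.

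Fosl2 kept its labelled group difference, 0.64, and passed only in the two-factor fit (0.64, adjusted p = 0.0444, over a range of adjusted p up to 0.977), with values between 0.44 and 0.84 when 1 library was left out. Its stem difference of -0.33 did not pass in any setting with all 4 libraries. With 1 library left out it ranged from -0.68 to 0.0282, the latter without CT26_102. Fits with 1 library left out held no second term, so for either division they mix stem with suffix. The correlation across genes for the labelled group, 0.655, was 0.616 with pseudocount 0.1, 0.583 without the filter, 0.696 with the filter at FPKM 5 and 0.693 by Spearman. That for the stem, 0.723, was 0.658 without the filter and 0.753 with the filter at FPKM 5. Of 103 differences of named genes, 86 passed in the two-factor fit and not in the first, 16 lost their call without the filter, 8 with the filter at FPKM 5, 2 with pseudocount 0.1 and between 10 and 16 with 1 library left out, up to 3 gained a call with 1 library left out and 1 among protein-coding genes, and rescaling and the eBayes settings changed none of the calls. For the remaining changes the cause was not tested. Depth limits values near the FPKM of 1 read, and fold sizes of genes with low values.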

Other observations

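The tests of scale, of Fosl2 against the labels, of length for the ribosomal, oxidative phosphorylation and interferon lists, of the segments against the interferon list and of fibroblast genes were chosen after their results were seen. The tests of length for the p53 and mitosis lists, of the gene order and of the neighbours of Fosl2 were chosen before.

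Further genes followed the suffix R, which marks the libraries labelled FOSL2-KO with chemoradiotherapy. The small heat shock protein Cryab rose from 27.2 to 229 and from 29.6 to 169 FPKM, and Marcksl1, an actin-binding substrate of protein kinase C, from 13.2 to 136 and from 9.68 to 59.6. The osteocalcin gene Bglap, which shares sequence with Bglap2, went from 0.172 to 11.4 and from 0.0701 to 6.29. The lysosomal galactosidase Glb1, often read as an activity in senescent cells, fell at the transcript level, from 23.5 to 8.61 and from 18.8 to 4.76 FPKM. The prostaglandin synthase Ptgs2 rose from 43.9 to 224 and from 108 to 299, and Ddit3, a stress transcription factor, was at 39.4, 226, 148 and 236 FPKM without passing (two-factor adjusted p = 0.0677).

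Between stems, the interleukin-33 receptor gene Il1rl1 was higher in stem CT26_102, at 76.5 and 177 FPKM against 12.1 and 18, and so were Fasn, at 45.8 and 21.5 against 18.7 and 10.1, and the chaperone gene Calr, at 742 and 697 against 407 and 387. The nonclassical MHC class I gene H2-T23 was lower, at 0.350 and 0.235 against 3.86 and 2.69.

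The first pattern is Fosl2, which was higher in the libraries labelled FOSL2-KO, together with higher medians of p53 targets and lower medians of mitosis genes there. Scale is argued against for both, since Fosl2 kept a log2 difference of at least 0.58 and the p53 list a median of at least 1.26 under both rescalings, and the trend with gene length is argued against by a p53 median of 1.35 and a mitosis median of -0.53 once that trend was removed. A loss of Fosl2 transcript in the libraries labelled FOSL2-KO is also argued against as the source, since the smaller of both Fosl2 differences was 0.56 upward, although protein was not measured here and an edited gene can keep its transcript. Genotype labels that follow the suffix while the genotype follows the stem stay open: Fosl2 was lower in both CT26_102 libraries, but the two-factor adjusted p of 0.130 does not decide it. The lower Fosl2 in stem CT26_102 may also come from its surroundings, since the 20 coding genes on each side of it on chromosome 5 had a median stem difference of -0.26 (limits -0.41 to -0.03), so that an effect on Fosl2 alone and lower surroundings both remain. Fosl2 and these neighbours (31036036 to 34486456) lie outside the chromosome 5 segment beyond all shuffles, which ends at 30674830. For the difference by suffix, chemoradiotherapy, which the labels name, remains as well, since no test here separates it from genotype.

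The second pattern is the difference between stems, with lower medians of ribosomal, oxidative phosphorylation and interferon genes and, for 9.188% of called genes, blocks of neighbouring genes. A chance order of genes is argued against by 8 segments beyond all shuffled orders in both pairs, which is consistent with a difference in chromosome copies between separate sublines, a hypothesis that no DNA measurement tests here. Removal of the length trend left medians of -0.24 for ribosomal genes (limits -0.28 to -0.20) and -0.86 for interferon genes (limits -1.18 to -0.50). Within these libraries the trend is argued against as the whole cause for both lists, although ribosomal genes stood at percentiles 7.92 and 10.32 among random lists of like expression. For oxidative phosphorylation genes it cannot be told apart, since the limits around -0.24 run from -0.37 to -0.08. All these limits are over genes, which are not independent, so they do not cover the spread between libraries. The segments hold 4.0% of the interferon genes that fell (1 of 25), against 4.726% of tested genes. A position inside the segments thus does not account for that list. Whether genes in the segments act on interferon genes elsewhere was not tested. The highest FPKM of Dcn, Lum, Thy1 and Dpt in the stem CT26_102 libraries was 0.142. This argues against fibroblasts that express these genes as the source of Col3a1 and similar genes. Dcn, Lum, Thy1 and Dpt were picked after their values were seen, however. Of 9 tested fibroblast markers, 4 rose and 1 fell in stem CT26_102 (median 0.51), so other fibroblasts are not excluded. What the stems differ in by design stays open because the labels do not say it.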
